A study of Mus musculus with 40 samples.

How the data were processed

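RNA from the colon and the small intestine of 20 female mice was measured on 40 Illumina MouseRef-8 BeadChip arrays, 1 array per sample. Per the labels, 500 ng of total RNA was amplified with a biotin label and 750 ng of the product was hybridized per array. The deposited non-normalized table gives a linear signal intensity for each probe and array that is not normalized between arrays and is already background-subtracted: between 21.4% and 25.1% of its values per array lie below 0. Beside each intensity the deposited table gives a detection value whose cells hold 1 minus the detection p-value, as the rise of the cells with the intensity showed. A deposited normalized table gives log2 values that are quantile-normalized between arrays, with a floor near 0. The submitters' processing notes name limma without a version or a role, and the scanner software is not stated. Columns were assigned to samples by the codes that the labels and the table headers share.

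The 10 columns of VSL#3 colon samples in the normalized table followed the arrays of the other strain in the non-normalized table, so the non-normalized table was used for every comparison and the normalized table for an alternative. Intensities were background-corrected with the detection p-values (limma neqc, offset 16), log2-transformed and quantile-normalized over the 40 arrays, with limma 3.58.1 in R 4.3.3. Of 25697 probes, 23978 had 1 gene symbol each in the annotation of the array platform, which gave 16593 symbols after a check against a RefSeq gene table (assembly GRCm38.p6, used for names only), and the 1719 probes without a symbol were left out. A probe was kept for a fit when its detection p-value was under 0.05 on at least 5 arrays of that fit, and each gene was represented by its kept probe with the highest mean over the 40 arrays. This gave 9833 genes in colon, 9634 in small intestine, 9200 in both and 10262 in either.

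Each tissue was fitted with limma over its 20 arrays as 4 group means of 5 mice, and contrasts were tested with moderated statistics at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were VSL#3 against PBS in each strain, the difference of that effect between the strains, and BALB/c against C57BL/6 in PBS mice. Comparisons between tissues used each mouse's colon minus small intestine log2 difference, since both samples of a mouse share its code in the labels. The values of each array, less the mean of its group, correlated between the colon and the small intestine of the same mouse over genes with a mean r of 0.186, and over 0.1 in 14 of 20 mice. Mice of different groups that share a number in the sample titles also share the letter of their source code, A for numbers 1 to 3 and B for 4 and 5. For title number 5 the source names carry another number in all groups but C57BL/6 PBS. Their deviations correlated with an r over 0.1 in 4 of 5 same-numbered pairs of PBS and VSL#3 BALB/c colon and in 0 of 5 in each other pair of groups checked, so the number was used as a block in an alternative alone.

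A total of 38 gene lists of intestinal cell types and pathways was fixed before the data were examined, as were the contrasts, the naming rule and most alternatives. Lists with at least 5 tested members, 35 in colon and 34 in small intestine, were tested with limma camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a contrast. Members were also adjusted over their list alone. This ignores other lists and genes and was not compared with chance, so a pass there calls no gene. Camera with an estimated correlation and fry (directional) served as alternatives, and a two-sided exact permutation test on the list scores of 5 against 5 arrays was added after the results were seen. The smallest p that exact test can give is 0.00794, so that at least 6 lists must reach it before any passes the adjustment, and a count of 0 there is weak evidence against a list. A list score is the mean over members of their log2 values, each centred over the arrays of the tissue. Named genes followed a rule. For VSL#3 contrasts, they were the 12 largest rises and falls past the threshold and, where under 5 genes passed, the 5 with the smallest p. For strain and tissue contrasts, they were the 12 largest rises and falls among genes whose groups did not overlap. To these came the 4 members with the smallest p of each called list, genes that check the labels, and the cytokines Il10, Ifng, Tnf, Il17a, Il6, Il1b and Tgfb1 with Reg3b and Reg3g where detected. A fold against a group in which no array detected the gene was computed against the detection limit and is given as at least that many fold. Where only some arrays of a group detected the gene, the difference includes values near the background. Where another kept probe of a named gene showed under 50% of the difference between 2 groups, its value is given, and other probes were not compared for the differences of effects.

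The steps were tested on simulated data with the measured spread. In the 4 contrasts of VSL#3 against PBS, between 89.6% and 94.0% of genes simulated with a log2 change of 1 were recovered. Of those with 0.5, between 31.3% and 50.7% were. Simulated genes varied independently of each other and many were changed at once, which loosens the adjusted threshold. These shares can therefore overstate recovery in the real contrasts. There, 32 genes in BALB/c colon, 31 in C57BL/6 colon, 9 in BALB/c small intestine and 4 in C57BL/6 small intestine differed by over 1 log2, and 0 passed. The precision of array values is limited by the number of arrays, and the median 95% confidence interval of a VSL#3 effect reached 0.32 log2 to each side. Alternatives changed the deposited table, the background correction, the normalization, the detection filter, the choice of probe, the weights, the variance prior, the arrays in the fit, the blocks, the pairing of tissues and the arrays left out. Added after the data were seen were alternatives without 3 or 7 colon arrays that held pancreatic transcripts, with that score as a covariate, and with values under 1 set to 1.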

Results

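Gene expression was measured in colon and small intestine tissue of 9-week-old female BALB/c and C57BL/6 mice that had received VSL#3, a mixture of live probiotic bacteria, or PBS by gavage in a volume of 200 µl, 3 times a week for 4 weeks. The 20 mice formed 4 groups of 5 by strain and treatment, and both tissues of each mouse were measured, which gave 8 groups of 5 arrays. Between 11898 and 13518 of 25697 probes were detected per array, or 46.3% to 52.6%, and arrays of the same group correlated with r between 0.973 and 0.988 over probes. The 2 strains came from different suppliers, so that strain and supplier cannot be separated. Source codes of the mice likewise differ between the 4 groups, so that code and group cannot be separated. Values are normalized log2 signals, differences are log2 with the standard error (SE) of the limma fit, and every group holds 5 mice.

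Genes with known distributions separated the arrays as labelled. Xist, the RNA of the inactive X chromosome, was detected on 40 of 40 arrays with both of its probes, and the Y-linked genes Kdm5d and Eif2s3y on 0, while the Y-linked Uty passed the detection threshold on 24 arrays at signals of at most 6.30. H2-Ea, an MHC class II chain whose gene is defective in C57BL/6 mice, ranged from 11.78 to 13.57 in BALB/c and from 4.66 to 6.98 in C57BL/6 mice. Sis (sucrase-isomaltase) ranged from 13.03 to 13.84 in small intestine and from 4.44 to 7.05 in colon, and Fabp6 and Apoa4 likewise separated the tissues. Aqp8 (a water channel of colonocytes) ranged from 11.07 to 11.58 in colon and from 4.67 to 5.92 in small intestine, with Car4 and Slc26a3 also higher in every colon array. Cdx1, a transcription factor of the intestinal epithelium, was detected on every array, whereas Fabp2, Hoxb13 and Slc10a2 lay near the background in both tissues and did not separate them.

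In the colon of BALB/c mice, the 5 genes with the smallest p between VSL#3 and PBS were Tnfrsf19, a receptor of the TNF receptor family (-0.64, SE 0.12), Wnt4, a Wnt ligand (-0.66, SE 0.17), Gamt, an enzyme of creatine synthesis (0.81, SE 0.21), Mmp9, a matrix metalloproteinase (-0.59, SE 0.15), and Hspa1a, an inducible heat shock protein (1.23, SE 0.33, with means of 7.72 against 6.49). None of them passed the test. Of the cytokine and antimicrobial genes detected, Il1b differed by 0.23 (SE 0.31), Tgfb1 by 0.05 (SE 0.19), and the epithelial antibacterial lectins Reg3b and Reg3g by -0.96 (SE 0.83; -0.04 with another Reg3b probe) and -0.86 (SE 0.60). Among the gene lists, pancreatic acinar markers were shifted up with a median of 1.88, with 22 of 25 members above 0 and none past the test (adjusted p = 2.45e-05, and 0.763 with an estimated correlation). Prss3 stood at 1.5, Ctrc at 1.98, 2210010C04Rik at 1.68 and Cela1 at 0.79. Cell cycle genes were shifted up (median 0.15, 26 of 30 above 0, adjusted p = 0.763 with an estimated correlation), as were immediate early genes (median 0.14, 14 of 18 above 0; adjusted p = 0.583 with an estimated correlation). Among cell cycle genes, Ccne2 stood at 0.30, Cdk1 at 0.38, Tk1 at 0.34 and Cdca3 at 0.39 (0.08 with its other probe). In the immediate early list Fos, a transcription factor induced within minutes of stimulation, differed by 0.61 (adjusted p = 0.0488 over the list alone). Atf3 differed by 0.51, Jun by -0.33 and Fosb by 0.58. Cholesterol synthesis genes were shifted down (median -0.13, 16 of 18 below 0, adjusted p = 0.763 with an estimated correlation). Insig1 stood at -0.31, Hmgcs1 at -0.30, Hsd17b7 at -0.27 and Cyp51 at -0.33. Over all genes, limma called 0 of 9833 genes, with 337 at an unadjusted p under 0.05 where chance gives 492, and 59 genes did not overlap between groups, or 0.6% where chance gives 0.794%. Adjusted over the list alone, 5 members of all lists passed, and fry and the exact permutation test called 0 lists. Without the 3 colon arrays with the highest acinar score, 2 genes passed and the acinar median was -1.06. Leaving out 1 array at a time gave from 2 list calls (without VSL#3 replicate 1) to 7 (without VSL#3 replicate 5).

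In the colon of C57BL/6 mice, the smallest p values belonged to Ccn2, a secreted matrix-associated protein (0.90, SE 0.17, with means of 10.90 against 10.01), Gpsm1 (-0.57), Golga4 (-0.58), Gpr3, an orphan receptor (0.46), and Gramd4 (0.54), none of which passed. Reg3g differed by 1.17 (SE 0.60), Reg3b by 0.60 (SE 0.83), Tgfb1 by 0.32 (SE 0.19) and Il1b by 0.00 (SE 0.31). Markers of B cells and follicles were shifted up (median 0.56, 18 of 20 above 0, adjusted p = 8e-11, and 0.301 with an estimated correlation). Vpreb3, a B cell protein, differed by 0.76 (adjusted p = 0.0412 over the list alone). Beside it stood Cxcl13 (0.82), a chemokine that draws B cells into follicles, Fcrla (0.84) and Tnfrsf13c (0.86). MHC class II genes, which present antigen to helper T cells, were shifted up (median 0.78, 11 of 12 above 0, adjusted p = 4.09e-07, and 0.301 with an estimated correlation). H2-Ob stood at 0.84, H2-Aa at 0.93, Ciita at 0.77 and H2-DMb2 at 0.52. Adipocyte markers were shifted down (median -0.51, 12 of 13 below 0, adjusted p = 3.42e-06, and 0.301 with an estimated correlation). Adig stood at -0.73, Lpl at -0.55, Aoc3 at -0.31 and Adipoq at -0.94. Weaker shifts up were those of cell cycle genes (median 0.14, adjusted p = 0.818 with an estimated correlation), T cell markers (median 0.23, adjusted p = 0.818 with an estimated correlation) and immediate early genes (median 0.26; adjusted p = 0.479 with an estimated correlation). Among cell cycle genes, Pcna stood at 0.59, Rrm1 at 0.44, Mcm6 at 0.55 and Uhrf1 at 0.46. Among T cell markers, Cd8b1 stood at 0.49, Cd3g at 0.58, Cd3d at 0.49 and Lat at 0.43. Of the immediate early genes, Ccn1 differed by 1.16 (0.19 and 0.65 with its other probes, adjusted p = 0.013 over the list alone). Btg2 differed by -0.80, Fosb by 0.61 and Gadd45b by 0.34. Fatty acid oxidation genes (median -0.12, adjusted p = 0.541 with an estimated correlation) and pancreatic acinar markers (median -1.12, adjusted p = 0.891 with an estimated correlation) were shifted down. Among fatty acid oxidation genes, Angptl4 stood at -0.80, Acaa1b at least 1.35-fold lower, Decr1 at -0.30 and Slc25a20 at -0.18. Among pancreatic acinar markers, Ctrl stood at -1.63. By limma, 0 of 9833 genes passed, with 633 at an unadjusted p under 0.05 where chance gives 492. Between groups 85 genes (0.864%, against 0.794% by chance) did not overlap. Adjusted over the list alone, 2 members of all lists passed, and fry and the exact permutation test called 0 lists. Ccn2 passed with the mouse number as a block, the only gene to do so, and Sprr2b (-1.07 with all arrays) was the 1 gene to pass when PBS replicate 4 was left out. The acinar median was 0.32 without PBS replicate 3. The list calls ranged from 3 without VSL#3 replicate 1 to 10 without VSL#3 replicate 4.

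In the small intestine of BALB/c mice, Hspa1a again stood among the 5 genes with the smallest p (1.70, SE 0.33, with means of 7.30 against 5.60), with Mettl14, a subunit of the RNA m6A methyltransferase detected on 0 VSL#3 and 3 PBS arrays, Nat8 (-0.68), Msmo1, a sterol oxidase of cholesterol synthesis (-0.76), and Ccdc117 (0.51), and none passed over all genes. Reg3b differed by 0.00 (SE 0.11), Reg3g by -0.08 (SE 0.19), Il1b by 0.12 (SE 0.16) and Tgfb1 by 0.13 (SE 0.19). Interferon response genes were shifted up (median 0.40, 27 of 31 above 0, adjusted p = 3.36e-10, and 0.315 with an estimated correlation). Adjusted over the list alone, 7 of them passed, each above 0. These included the GTPases Irgm2 (0.93) and Gbp2 (0.63), the peptide transporter Tap1 (0.76) and the chemokine Cxcl10 (0.90), each at adjusted p = 0.0301. MHC class II genes were shifted up (median 0.29, adjusted p = 0.368 with an estimated correlation), and 5 passed over the list alone. H2-DMb1 stood at 0.66, H2-Ab1 at 0.40, Cd74 at 0.34 and Ciita, the transactivator of these genes, at 0.50. Cholesterol synthesis genes were shifted down (median -0.17, 17 of 18 below 0, adjusted p = 1.93e-06, and 0.315 with an estimated correlation). Msmo1 had an adjusted p of 0.00508 over the list alone. Idi1 stood at -0.49, Sqle at -0.38 and Lss at -0.42. Absorptive genes were shifted down (median -0.18, 22 of 25 below 0, adjusted p = 0.368 with an estimated correlation). The glucose transporter Slc2a2 stood at -1.19, the peptide transporter Slc15a1 at -0.54, Rbp2 at -0.55 and Treh at -0.32. Heat shock genes were shifted up (median 0.12, adjusted p = 0.406 with an estimated correlation). Over the list alone, Hspa1a (adjusted p = 0.00105) and its co-chaperone Dnajb1 (0.55, adjusted p = 0.00336) passed. Herpud1 stood at 0.23 and Hsph1 at 0.78. Smooth muscle markers were shifted up (median 0.22, adjusted p = 0.368 with an estimated correlation). Actg2, a smooth muscle actin, differed by 0.43 (adjusted p = 0.0412 over the list alone).

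Further lists shifted up in BALB/c small intestine were cell cycle genes (median 0.17, adjusted p = 0.368 with an estimated correlation), T cell markers (median 0.22, adjusted p = 0.442 with an estimated correlation), adipocyte markers (median 0.29, adjusted p = 0.442 with an estimated correlation) and Toll-like receptor and NF-kB genes (median 0.07, adjusted p = 0.333 with an estimated correlation). Among cell cycle genes, Tpx2 stood at 0.38, Rrm2 at 0.54 (0.22 with its other probe), Ube2c at 0.44 and Top2a at 0.32. Among T cell markers, Cd7 stood at 0.44, Cd6 at 0.67, Cd8b1 at 0.40 and Ccl5 at 0.56. Among adipocyte markers, Aoc3 stood at 0.52, Lpl at 0.74, Adipoq at 1.08 and Car3 at 1.17. Among Toll-like receptor and NF-kB genes, Nod1 stood at 0.40, Lbp at least 1.19-fold higher, Myd88 at 0.27 and Ikbkb at 0.23. Those shifted down were xenobiotic metabolism (median -0.14, adjusted p = 0.333 with an estimated correlation), antimicrobial peptides and lectins (median -0.13, adjusted p = 0.315 with an estimated correlation), goblet cell genes (median -0.08, adjusted p = 0.266 with an estimated correlation), enteroendocrine markers (median -0.12, adjusted p = 0.368 with an estimated correlation) and pancreatic acinar markers (median -0.20, adjusted p = 0.368 with an estimated correlation). Among xenobiotic metabolism genes, Gstt1 stood at -0.54, Ces1f at -0.30, Gsta4 at -0.45 and Cyp2d26 at -0.73. Among antimicrobial peptides and lectins, Reg4 stood at -0.67, Reg1 at -0.39, Reg3a at -0.30 and Defa20 at -0.12 (0.08 with its other probe). Among goblet cell genes, Clca4a stood at -0.31, Muc1 at -0.38, Galnt12 at -0.31 and Tspan13 at -0.30. Among enteroendocrine markers, Sct stood at -0.29, Sst at -0.26, Nts at -0.49 (0.14 with its other probe) and Pyy at -0.18. Among pancreatic acinar markers, Sycn stood at -0.93, Cela1 at -0.24 and Ctrl at 0.35. None of the genes passed, as limma called 0 of 9634 genes, with 592 at an unadjusted p under 0.05 where chance gives 482. Between groups 83 genes (0.862%, against 0.794% by chance) did not overlap. Over all lists, 17 members passed adjusted over the list alone, and fry and the exact permutation test called 0 lists. Hspa1a passed with median scaling in place of quantile normalization and in a fit of the compared groups alone, and Mettl14 without background correction, with the normalized table, with values under 1 set to 1 and without PBS replicate 3. Nat8 passed without PBS replicate 1. List calls ranged from 7 without PBS replicate 3 to 16 without PBS replicate 1. Median scaling moved the median of all genes to 0.12.

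In the small intestine of C57BL/6 mice, interferon response genes were shifted down (median -0.26, 24 of 31 below 0, adjusted p = 2.33e-05, and 0.795 with an estimated correlation). Their members with the smallest p were Oas1g (-0.81), Oas2 (-0.93) and Oasl2 (-0.66), of the family that senses double-stranded RNA, and Usp18 (-0.98), a negative regulator of interferon signalling, and none passed. B cell markers were shifted up (median 0.31, 18 of 19 above 0), as were T cell markers (median 0.16) and cell cycle genes (median 0.11), and smooth muscle markers were shifted down (median -0.13). Among B cell markers, H2-DMb2 stood at 0.69, Ccr6 at 0.59 (0.03 with its other probe), Cd22 at 0.46 and Bcl11a at 0.30. Among T cell markers, Gzma was at least 1.02-fold lower, while Il7r stood at 0.30, Thy1 at 0.19 and Cd3e at 0.25. Among cell cycle genes, Mcm6 stood at 0.31 (0.03 to 0.28 with its other probes), Pcna at 0.33, Rrm2 at 0.40 (-0.18 with its other probe) and Mcm2 at 0.24. Among smooth muscle markers, Hspb6 stood at -0.32, Cnn1 at -0.61, Mustn1 at -0.20 (0.02 with its other probe) and Tagln at -0.25. Each of these 4 lists had an adjusted p of 0.795 with an estimated correlation. Single genes with the smallest p were Glyat, a glycine conjugating enzyme (at least 1.16-fold higher), the histone genes H4c18 (-0.58) and H4c11 (-0.40), Trp53inp1 (0.50) and Akip1 (0.72). Reg3g differed by 0.18 (SE 0.19), Reg3b by 0.00 (SE 0.11; 0.19 with its other probe), Il1b by -0.14 (SE 0.16) and Tgfb1 by -0.08 (SE 0.19). Limma called 0 of 9634 genes, with 407 at an unadjusted p under 0.05 where chance gives 482. Between groups 60 genes (0.623%, against 0.794% by chance) did not overlap. No list member passed when adjusted over the list alone, and fry and the exact permutation test called 0 lists. List calls ranged from 1 without VSL#3 replicate 1 to 11 without PBS replicate 5.

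**Figure D1:**
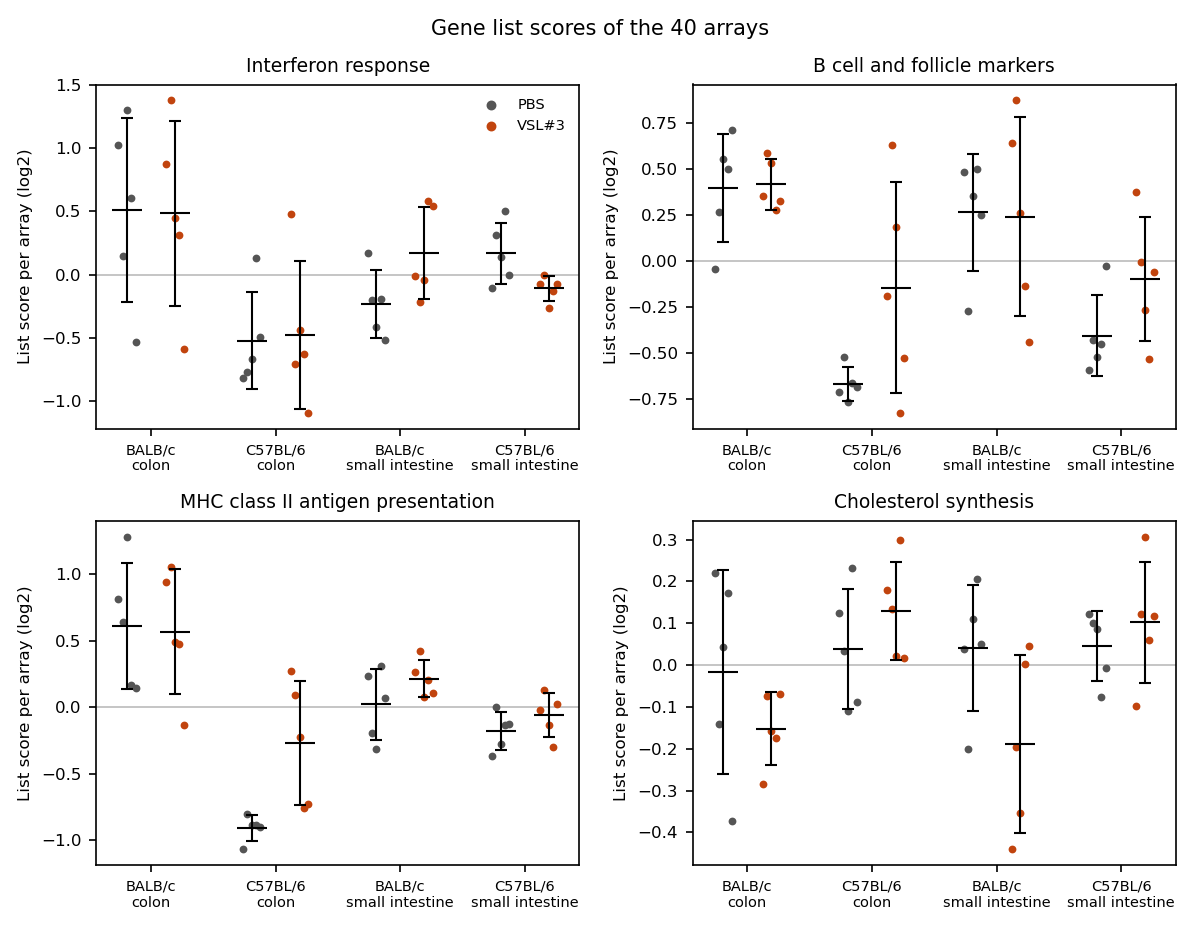
List scores (log2, centred over the 20 arrays of a tissue) of 4 gene lists for each array, with points for mice and bars for the mean and SD of 5 mice. In BALB/c small intestine the interferon list lay higher with VSL#3 and in C57BL/6 small intestine lower, with overlapping groups and medians of 0.40 and -0.26 over the members.

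The difference of the VSL#3 effect between strains was tested directly as the effect in BALB/c minus that in C57BL/6. In small intestine the interferon list differed most (median 0.65, 28 of 31 above 0, adjusted p = 8.01e-15, and 0.246 with an estimated correlation). Over the list alone 5 members passed, among them Usp18 (1.83), the antiviral enzyme Rsad2 (1.72), Cxcl10 (1.36) and Irgm2 (1.13). Cholesterol synthesis differed by a median of -0.21 and smooth muscle markers by 0.33 (adjusted p = 0.45 each with an estimated correlation). Adipocyte markers differed by 0.62 (adjusted p = 0.77 with an estimated correlation). Msmo1 stood at -0.94 (adjusted p = 0.018 over the list alone). Among cholesterol synthesis genes, Idi1 stood at -0.79, Insig1 at -0.38 and Sqle at -0.54. Among smooth muscle markers, Actg2 stood at 0.56, Hspb6 at 0.54, Ckb at 0.42 and Myh11 at 0.53. Among adipocyte markers, Aoc3 stood at 0.59, Car3 at 1.80, Lpl at 0.95 and Adipoq at 1.41. B cell markers differed by a median of -0.38, absorptive genes by -0.23 and goblet cell genes by -0.11. Their adjusted p with an estimated correlation were 0.85, 0.792 and 0.186. Among B cell markers, H2-DMb2 stood at -0.85, Cd79a at -0.64, Btla at -0.47 and Fcer2a at -0.47. Among absorptive genes, Slc2a2 stood at -1.26, Treh at -0.47, Slc15a1 at -0.63 and Slc5a1 at -0.37. Among goblet cell genes, Tspan13 stood at -0.61, Galnt12 at -0.48, Galnt3 at -0.57 and Clca4a at -0.35. Genes with the smallest p were Dnajb1 (0.86), the chemokine receptor Cxcr3 (0.81), Tra2a (0.67), Hspa1a (2.10, SE 0.47) and Crebzf (-0.94). Il1b differed by 0.27 (SE 0.23), Tgfb1 by 0.21 (SE 0.26), Reg3b by 0.00 (SE 0.16) and Reg3g by -0.26 (SE 0.27). Limma called 0 of 9634 genes, with 518 at an unadjusted p under 0.05 where chance gives 482. Fry called 0 lists, and 9 members passed adjusted over the list alone. Median scaling moved the median of all genes to 0.15.

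In colon the same difference was -0.70 for MHC class II genes, negative in 12 of 12 members (H2-DMb2 -0.91, H2-Ob and Ciita -1.0 each, H2-Oa -0.57), -0.59 for B cell markers (Vpreb3 -0.76, Btla -0.60, Cxcr5 -0.87), -0.29 for T cell markers (Gimap3 -0.51, Cd2 -0.46, the regulatory T cell factor Foxp3 -0.38, Cd6 -0.42) and -0.15 for macrophage and dendritic cell markers, each as the list median. Of the last, Clec7a, a receptor for fungal glucans, stood at -1.38 (adjusted p = 0.0438 over the list alone), beside Cx3cr1 (-0.61), Lyz2 (-0.76) and Adgre1 (-0.46). Pancreatic acinar markers differed by a median of 3.01 (Prss3 2.43, 2210010C04Rik 3.07, Cela1 1.32, Ctrl 3.36), cholesterol synthesis by -0.20 (Insig1 -0.48, Idi1 -0.74, Dhcr7 -0.44, Hsd17b7 -0.31), fatty acid oxidation by 0.20 (Acot1 0.52, Angptl4 0.71, Acaa1b 0.87, Etfb 0.30), adipocyte markers by 0.32 (Acvr1c 0.58, Thrsp 0.98, Adig 0.60, Lpl 0.34), circadian clock genes by -0.19 (Wee1 -0.58, Tef -1.13, Usp2 -0.68, Dbp -1.52) and smooth muscle markers by 0.07 (Tagln 0.52, Hspb6 0.28, Pgm5 0.32, Tpm2 0.26). Each of these 10 lists had an adjusted p of 0.501 with an estimated correlation. Genes with the smallest p were Gpsm1 (0.78), Creb3l2 (0.86), Tnfrsf19 (-0.81), Tie1 (-0.87) and Thap1 (0.84). Reg3g differed by -2.03 (SE 0.84), Reg3b by -1.56 (SE 1.18), Il1b by 0.23 (SE 0.43) and Tgfb1 by -0.27 (SE 0.27). Limma called 0 of 9833 genes, with 448 at an unadjusted p under 0.05 where chance gives 492. Fry called 0 lists, and 5 members passed adjusted over the list alone. Dbp and Tef passed without the 3 colon arrays with the highest acinar score, at -2.84 and -2.06, and the acinar median then was -1.42. Sprr2b (1.53) passed without C57BL/6 PBS replicate 4.

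The VSL#3 effect was also compared between the tissues of the same mice, as the effect in colon minus that in small intestine. In BALB/c mice xenobiotic metabolism differed by a median of 0.22 (Gstt1 0.73, Gsta1 0.55, Gsta4 0.58, Gsta2 0.68), absorptive genes by 0.13 (Rbp2 0.77, Slc6a19 0.38, Slc15a1 0.42, Dpp4 0.16) and Toll-like receptor and NF-kB genes by -0.14 (Nod1 -0.45, Traf6 -0.32, Myd88 -0.29, Tlr2 -0.47), each with an adjusted p of 0.603 with an estimated correlation. Interferon response genes differed by -0.35, adipocyte markers by -0.56 and pancreatic acinar markers by 1.37. Their adjusted p with an estimated correlation were 0.744, 0.66 and 0.678. Among interferon response genes, Cxcl10 stood at -1.29, Rtp4 at -0.53, Gbp2b at -1.04 and Tap1 at -1.06. Among adipocyte markers, Aoc3 stood at -0.63, Car3 at -1.84, Adipoq at -1.53 and Lep at -0.67. Among pancreatic acinar markers, Cela1 stood at 1.03, Sycn at 0.89, Reg1 at 2.4 and Clps at 1.46. In C57BL/6 mice MHC class II genes differed by 0.59 (adjusted p = 0.638 with an estimated correlation), interferon response genes by 0.21 (Rtp4 0.82, Oas1g 0.89, Psmb8 0.65, Dhx58 0.64) and B cell markers by 0.24 (Cxcr5 0.66, Fcrla 0.66, Fcmr 0.51, Cd79b 0.49), the last pair with an adjusted p of 0.986 with an estimated correlation. Among MHC class II genes, Ctss stood at 0.31, H2-Ob at 0.60, Cd74 at 0.76 and H2-DMa at 0.77. Genes with the smallest p were Fbxl15 (0.93), Specc1l (-0.55), Tmem218 (0.84), Rpl36a (0.51) and Mmp9 (-0.67) in BALB/c mice and Edn2 (-0.79), Nfkbie (0.81), Sf1 (-0.91), Nipal4 (0.89) and Gpr3 (0.62) in C57BL/6 mice. Reg3g differed by -0.78 (SE 0.69) and 0.99 (SE 0.69) in the 2 strains, Reg3b by -0.96 (SE 0.84) and 0.61 (SE 0.84), Il1b by 0.11 and 0.14 (SE 0.33 each) and Tgfb1 by -0.08 and 0.40 (SE 0.27 each). Limma called 0 of 9200 genes in both strains, with 790 in BALB/c and 390 in C57BL/6 at an unadjusted p under 0.05, where chance gives 460. In BALB/c 5 of 100 splits of the mice, the real one included, gave as many as 790, with a median of 439 in the others. In C57BL/6 65 of 100 splits gave as many as 390. Fry and the exact permutation test called 0 lists, and 3 members in each strain passed adjusted over the list alone. The interferon median in BALB/c mice was 0.19 without the mice of the 3 colon arrays with the highest acinar score. Camera then called the list in the opposite direction (adjusted p = 0.0270). BALB/c list calls ranged from 0 without PBS mouse 3 to 14 without PBS mouse 1. C57BL/6 list calls ranged from 1 without PBS mouse 3 to 6 without PBS mouse 4. Median scaling moved the median of all genes in BALB/c mice to -0.11.

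In the colon of PBS mice, BALB/c and C57BL/6 differed in 1164 of 9833 genes, of which 598 were higher in BALB/c and 566 lower. H2-Ea was higher by 7.29 (SE 0.37) against a C57BL/6 group near the background, where 2 of 5 arrays detected it, Gbp2b, an interferon-induced GTPase, 48.0-fold (5.58, SE 0.44), and the MHC class I gene H2-Q5 26.3-fold (4.72, SE 0.27), followed by Lpo (lactoperoxidase, 4.24), the clock output gene Dbp (3.88, SE 0.58), H2-K1 (3.52; -0.54 with its other probe), Chmp1a (3.10), Tmem87a (3.02), Ly6g6c (2.94) and AI467606 (2.76). H2-Q2 was at least 11.2-fold higher with the probe used, but -2.16 with its other probe, and the muscle actin Actc1 at least 5.38-fold higher (1.42 with its other probe). Mptx1, a mucosal pentraxin, was 68.1-fold lower in BALB/c (-6.09, SE 0.36), followed by Nxpe4 (-4.69), Abhd16a (-4.61), the protease cathepsin C (Ctsc, -4.55), Tor1aip2 (-3.78; -0.86 and 0.00 with its other probes), Casp9 (-3.44), St3gal4 (-3.37), Prcp (-3.33), Sprr2a1 (-3.28) and Chchd4 (-3.26). Fcer1g, the shared signalling chain of Fc receptors, was at least 11.0-fold lower and Thumpd1 at least 9.77-fold lower. For both, no BALB/c array detected the gene, and a sequence variant under the probe stays open.

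Of the 10 lists that camera called between the strains in colon, 0 held with an estimated correlation. B cell markers were higher in BALB/c (median 1.15), where 14 of 20 members rose, such as Ltb (lymphotoxin beta, 1.76), Vpreb3 (1.42), Fcer2a (0.95) and H2-DMb2 (1.35), or 17 adjusted over the list alone (adjusted p = 4.67e-11, and 0.233 with an estimated correlation). Of 18 T cell markers 9 rose (median 0.75), or 15 adjusted over the list alone (adjusted p = 0.233 with an estimated correlation), and of 8 plasma cell markers 3 rose (median 0.57, adjusted p = 0.233 with an estimated correlation). Among T cell markers, Cd27 stood at 1.40, Cd3e at 1.08, Gimap3 at 0.98 and Thy1 at 0.48. Among plasma cell markers, Pou2af1 stood at 1.57, Mzb1 at 1.19, Tnfrsf17 at 0.57 and Jchain at 0.80. Of 12 MHC class II genes 8 rose and 1 fell (median 1.77, adjusted p = 0.233 with an estimated correlation), and a different probe of H2-Ab1 had the opposite sign, at -3.17. H2-Ab1 stood at 2.49, Ciita at 1.96 and H2-Aa at -3.0. Interferon response genes were higher (median 0.91, 6 of 31 rose, 10 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation), as were macrophage and dendritic cell markers (median 0.32, 7 rose and 2 fell of 20, adjusted p = 0.497 with an estimated correlation). Among interferon response genes, Oasl1 stood at 1.41 (0.58 and 1.02 with its other probes), Rtp4 at least 1.45-fold higher and Psmb8 at 1.57. Among macrophage and dendritic cell markers, Fcgr3 stood at 1.61, Itgae at 1.44 and Lyz2 at 1.18 (0.58 and 1.20 with its other probes). Smooth muscle markers were lower (median -0.28, 6 of 23 fell, 8 adjusted over the list alone, adjusted p = 0.233 with an estimated correlation), and so was xenobiotic metabolism (median -0.27, 10 fell and 1 rose of 29, adjusted p = 0.233 with an estimated correlation). Among smooth muscle markers, Hspb6 stood at -1.18, Pgm5 at -1.45, Synm at -0.78 and Mustn1 at -0.51 (0.02 with its other probe). Among xenobiotic metabolism genes, the glutathione transferases Gsta3, Gsta2 and Gsta1 stood at -1.64, -1.22 and -1.38 and Cyp2c65 at -2.70. Cell cycle genes (median -0.22, adjusted p = 0.583 with an estimated correlation) and enteric neuron and glia markers (median -0.24, adjusted p = 0.497 with an estimated correlation) had 1 member each past the test over all genes. Among cell cycle genes, Cdca3 fell by 1.12, with Ccne2 at -0.45, Tk1 at -0.62 (-0.20 with its other probe) and Kif11 at -0.59. Among enteric neuron and glia markers, the neuropeptide gene Gal fell by 1.54, with Syt11 at -0.33, Npy at 0.71 and Uchl1 at -0.42. Reg3b differed by -0.69 (SE 0.83), Reg3g by -0.35 (SE 0.60), Il1b by 0.47 (SE 0.31) and Tgfb1 by 0.21 (SE 0.19). Fry called 10 lists, of which 7 were among the 10 that camera called, and the exact permutation test called 8. Acinar transcripts raised 2 of the 5 BALB/c and 1 of the 5 C57BL/6 PBS arrays, and without the 7 colon arrays with a raised score 683 genes passed.

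In the small intestine of PBS mice, the strains differed in 1052 of 9634 genes, with 507 higher and 545 lower in BALB/c. Alpha-defensins, the antimicrobial peptides of Paneth cells, went both ways: Defa31 (6.85, SE 1.04) and the defensin-like AY761185 (6.83, SE 0.77) were higher in BALB/c, and Defa22 was lower (-7.95, SE 0.82). Leaving out 1 array at a time, they ranged from 5.96 to 7.47, from 6.25 to 7.32 and from -8.54 to -7.27. H2-Ea was higher by 7.29 (SE 0.36), with C57BL/6 again near the background and 3 of 5 arrays detected, beside H2-Q5 (3.84), Glycam1, a ligand of L-selectin (3.48), Serpina10 (3.33), Abhd1 (3.0), Dbp (2.95), Chmp1a (2.87) and Tmem87a (2.82), while H2-Q2 was at least 16.8-fold higher (-3.71 with its other probe) and H1f10 at least 9.94-fold. Lower in BALB/c were Cfl2 (-6.16; -0.03 with its other probe), Ctsc (-4.91), H2-Aa (-4.70), the skeletal muscle actin Acta1 (-4.53), Tor1aip2 (-4.17; -1.21 and -0.33 with its other probes) and Abhd16a (-4.10). St3gal4 was at least 45.9-fold lower, Fcer1g at least 15.7-fold, ccdc198 at least 13.3-fold, Taf4 at least 12.5-fold and Aldh1a7 at least 10.2-fold. Of 18 antimicrobial peptides and lectins 6 fell and 1 rose (median -0.32, adjusted p = 0.147 with an estimated correlation), and Reg3g differed by -0.62 (SE 0.19, adjusted p = 0.039) and Reg3b by -0.25 (SE 0.11). The call of Reg3g was lost with median scaling, with the normalized table and with values under 1 set to 1 (-0.61 to -0.63, adjusted p from 0.0580 to 0.0898). Defa21 stood at -3.09, Ang4 at -1.95 and Itln1 at -1.17. B cell markers (median 0.72, 9 of 19 rose) and T cell markers (median 0.32, 5 of 23) were higher. So was oxidative phosphorylation (median 0.14, 1 of 51). Each had an adjusted p of 0.65 with an estimated correlation. Of the last, Ndufa4 rose by 0.28, with Ndufs7 at 0.28, Ndufb10 at 0.73 and Cox5b at -0.28. Among B cell markers, Ltb stood at 1.12, the chemokine receptor Ccr6 at 1.29 (0.63 with its other probe), H2-DMb2 at 1.03 and Fcer2a at 0.92. Among T cell markers, Cd27 stood at 1.35 (0.62 with its other probe), Gimap3 at 0.98, Il7r at 0.73 and Lat at 0.64.

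Interferon response genes in small intestine were lower in BALB/c (median -0.28, 5 of 31 fell and 1 rose, adjusted p = 0.65 with an estimated correlation), whereas in colon the list was higher. Psmb9 stood at -2.64, Oasl2 at -1.40, Gbp2 at -0.91 and Gbp2b at 1.58. Smooth muscle markers were lower (median -0.35, 7 of 22 fell, 11 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation), and so were genes of the colonocyte list that small intestine expresses (median -0.22, 4 of 19 fell, adjusted p = 0.411 with an estimated correlation). Among smooth muscle markers, Hspb6 stood at -1.39, Pgm5 at -1.93, Actg2 at -0.82 and Synm at -0.76. Among colonocyte genes, Gsdmc2 stood at -2.76, Ly6d at least 2.56-fold lower, Ceacam20 at -0.76 and Scnn1a at -0.58. Il1b differed by 0.06 (SE 0.16) and Tgfb1 by -0.18 (SE 0.19). Fry called 9 lists, of which 4 were among the 7 that camera called. The exact permutation test called 0, with 13 lists at an exact p under 0.05 and a smallest adjusted p of 0.0675. The tissues shared 226 genes higher and 290 lower in BALB/c, where independence gives 30.5 and 30.7. Another 4 in each direction were opposite. Both tissues come from the same mice and were read with mostly the same probes, so that independence is a reference value and not a test. Of the strain differences of PBS mice, 98.4% in colon and 97.1% in small intestine had the same sign in VSL#3 mice. Those are different animals, but a sequence variant under a probe would recur in them. A test of the strain difference between tissues, added after the results were seen, called 283 of 9200 genes, 138 of them higher in colon. Examples picked from the genes with small p were Cfl2, which differed by 6.11, Serpina1b by 3.90 and Nxpe4 by -4.04. Camera called 11 lists there, of which 0 held with an estimated correlation, with the lowest adjusted p for MHC class II genes (median 1.59, 0.178), macrophage and dendritic cell markers (median 0.49, 0.261), and interferon response and xenobiotic metabolism genes (medians 1.36 and -0.30, 0.433 each). Genes of the circadian clock list differed both ways between strains in both tissues, so that the list median was 0.06 in colon and -0.11 in small intestine and camera did not call it, while Tef (2.02 and 1.53), Nr1d1 (1.97 and 1.80), Nr1d2 (1.40 and 1.70, the latter 0.79 with its other probe) and Arntl (-1.22 and -0.91), singled out after their values were seen, each passed in both tissues.

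**Figure D2:**
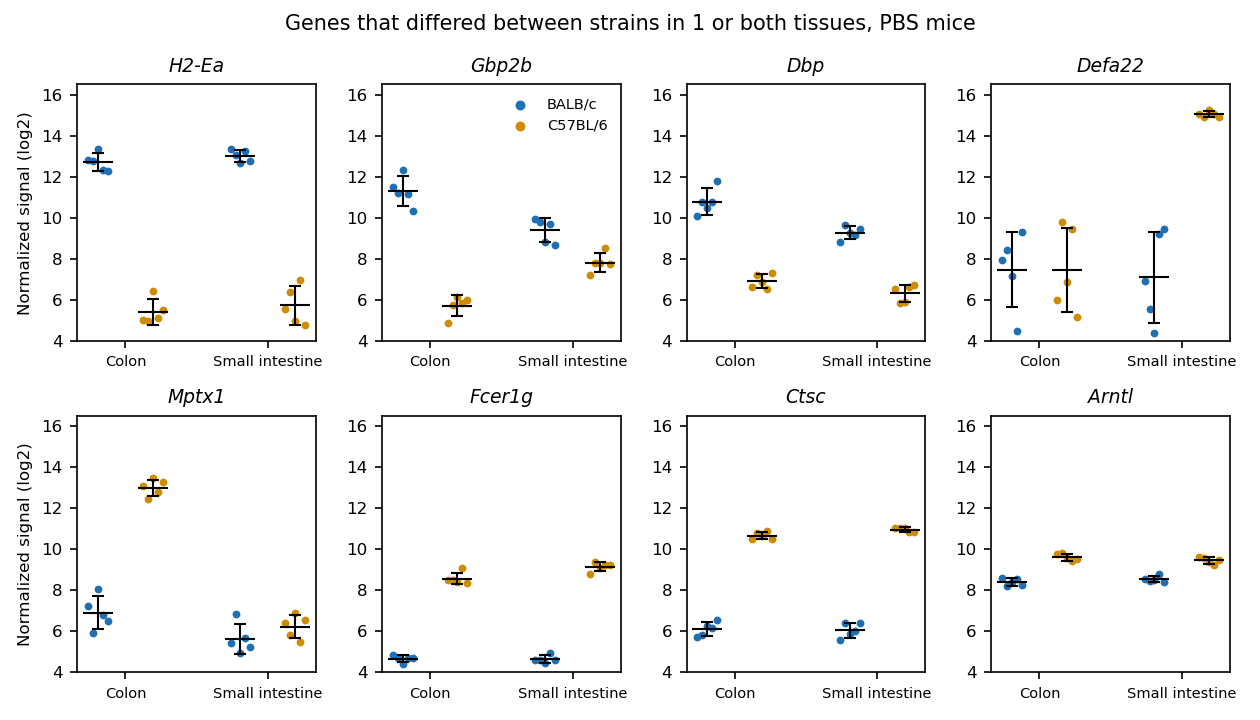
Normalized signal (log2) of 8 genes in PBS mice, with points for mice and bars for the mean and SD of 5 mice, chosen from the genes in the text to show both directions. H2-Ea was higher in BALB/c by 7.29 in both tissues, Fcer1g was near the background in BALB/c, and Defa22 was lower in BALB/c small intestine by -7.95 but low in colon in both strains.

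Colon and small intestine of the same PBS mice differed in 4129 of 10262 genes in BALB/c (2393 higher in colon and 1736 lower) and in 4293 in C57BL/6 (2475 and 1818). Transporters and enzymes of colonocytes were higher in colon, such as the proton pump Atp12a (7.25, SE 0.25, in BALB/c and 6.53, SE 0.25, in C57BL/6) and Aqp8 (6.18 and 5.82, SE 0.15 each), as were Retnlb, a goblet cell product (6.66 and 6.81), Insl5, a hormone of colonic endocrine cells (5.91, and at least 47.8-fold), Wfdc2 (7.81 and 6.70), Sycn, a zymogen granule protein (7.88 and 8.21), and the carbonic anhydrase Car2 (at least 43.6-fold, and 6.43). St6galnac6 was at least 43.1-fold and 42.6-fold higher (with other probes down to 2.68 and 2.75), Cyp2d34 at least 38.2-fold and 32.3-fold, and Nxpe2 at least 29.5-fold and 44.6-fold, with B3galt5 (5.44) and Cyp2d12 (5.29) named in BALB/c and Mptx1 (6.77) and Hao2 (5.90) in C57BL/6. Higher in small intestine were the apolipoprotein Apoa1 (-8.17 and -7.84), Sis (-8.05 and -7.55), the scaffold protein Pdzk1 (-7.51 and -7.39), Lgals2 (-7.99 and -6.96), the lectins Reg3a (-7.46 and -7.08), Reg3b (-6.08 and -5.64) and Reg3g (-6.67 and -6.93), and the ileal bile acid binding protein Fabp6 (-7.42 and -6.67). Defensins led the differences of each strain, with Defa31 (-9.78), AY761185 (-9.40) and Defa26 (-7.60) in BALB/c and Defa39 (-8.24), Defa21 (-8.18), Defa22 (-7.59) and Defa26 (-7.40) in C57BL/6, beside Slc51a (-7.48), Prap1 (-7.37) and Naaladl1 (-7.15) in BALB/c and Anpep (-7.09) in C57BL/6. Il1b differed by 0.19 and -0.22 (SE 0.23 each) and Tgfb1 by -0.06 and -0.44 (SE 0.19 each), without passing the test.

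Region-specific lists followed the tissue in both strains, and 3 held with an estimated correlation. Small intestinal absorptive genes were higher in small intestine (median -4.49, 25 of 25 fell in BALB/c, and -4.58, 24 of 25 in C57BL/6), such as the amino acid transporter Slc6a19 (-6.15 and -5.84), the peptidases Dpp4 (-3.78 and -3.79) and Anpep (-7.13 in BALB/c), and Xpnpep2 (-4.85 and -5.95), with adjusted p = 0.000207 and 0.000283 with an estimated correlation. Distal bile acid genes were higher in small intestine (medians -4.46 and -4.23, 7 of 8 fell in each strain), with Amn (-6.11 and -5.80), the enterokine Fgf15 (-4.99, and at least 21.8-fold lower) and Slc51b (-3.93 and -3.73), and adjusted p = 0.0185 and 0.0219 with an estimated correlation. Colonocyte genes were higher in colon (medians 2.29 and 1.78, 17 of 26 rose and 2 fell in BALB/c, 19 and 4 in C57BL/6), with Aqp4 (4.18 and 4.37), Gsdmc2 (4.75 in BALB/c) and Scnn1a (2.78 in C57BL/6), and adjusted p = 0.00806 and 0.0181 with an estimated correlation. The other lists that camera called did not hold with an estimated correlation, where their adjusted p ranged from 0.085 to 0.759.

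Of these, goblet cell genes were higher in colon (medians 0.54 and 0.87, 8 and 12 of 17 rose, adjusted p = 0.337 and 0.176 with an estimated correlation), as were smooth muscle markers (medians 0.87 and 0.81, adjusted p = 0.291 and 0.274 with an estimated correlation) and fibroblast and matrix genes (medians 0.72 and 0.42, adjusted p = 0.191 and 0.428 with an estimated correlation). Among goblet cell genes, Muc1 was at least 4.84-fold higher in BALB/c (with other probes down to 1.08) and stood at 2.15 in C57BL/6, Ern2 at 1.46 and 1.44, Bcas1 at 1.31 and 1.24 and Clca1 at 1.37 and 1.64. Among smooth muscle markers, Tagln stood at 2.17 and 2.09, Actg2 at 1.72 and 1.14, Smtn at 1.28 and 1.25, Des at 1.71 in BALB/c and Mustn1 at 1.11 in C57BL/6. Among fibroblast and matrix genes, Loxl1 stood at 1.44 and 0.91, Mfap5 at 2.06 and 1.38, Serpinf1 at 1.40 and 1.16, Sparc at 0.94 in BALB/c and Dpt at 0.76 in C57BL/6. T cell markers were lower in colon (medians -0.88 and -0.92, 15 of 23 fell in each strain, adjusted p = 0.313 and 0.185 with an estimated correlation). Cd8b1 stood at -1.79 and -2.0, Cd160 at -1.38 and -1.71, Cd3e at -1.36 and -1.93, Lat at -1.11 in BALB/c and Cd3g at -2.61 in C57BL/6. Antimicrobial peptides and lectins were lower in colon (medians -2.72 and -3.85, 10 of 18 fell in each strain, and 3 and 4 rose, adjusted p = 0.107 and 0.176 with an estimated correlation), with Mmp7, the protease that processes defensins, at least 22.6-fold and 26-fold lower. Defa21 stood at -5.35 in BALB/c and Lyz1 at -2.65 in C57BL/6. Proximal genes were lower in colon (medians -0.80 and -0.37, adjusted p = 0.107 and 0.173 with an estimated correlation), as was xenobiotic metabolism (medians -0.84 and -0.46, adjusted p = 0.148 and 0.44 with an estimated correlation). Among proximal genes, Cps1 stood at -5.03 and -5.57, Rbp2 at -3.52 and -2.72, Otc at -3.10 and -2.47, Slc40a1 at 2.20 in BALB/c and Heph at -0.89 (-0.97 to -0.43 with its other probes) in C57BL/6. Among xenobiotic metabolism genes, Cyp3a25 was at least 18.0-fold and 14.8-fold lower, and Cyp1b1 stood at -1.85 in BALB/c and was at least 3.38-fold lower in C57BL/6. Sult1a1 went the other way, at 4.62 and 4.58, as did Gstm5, at 1.16 and 1.12.

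Cell cycle genes were lower in colon (medians -0.39 and -0.26, adjusted p = 0.759 and 0.596 with an estimated correlation), and ribosomal proteins were higher (medians 0.32 and 0.25, 31 of 44 rose in BALB/c and 25 in C57BL/6, adjusted p = 0.085 and 0.176 with an estimated correlation). Among cell cycle genes, Top2a stood at -0.68, Tk1 at -0.71, Cdca8 at -0.61 and Uhrf1 at -0.56 in BALB/c, and Mcm4 at -0.38, Ccne2 at -0.69, Mcm5 at -0.32 and Cdca8 at -0.55 in C57BL/6. Among ribosomal proteins, Rpl37 stood at 0.77, Rps15 at 0.50, Rpl9 at 0.53 and Rpl41 at 0.35 in BALB/c, and Rplp1 at 0.48, Rps19 at 0.46, Rpl38 at 0.44 (-0.26 with its other probe) and Rpl41 at 0.34 in C57BL/6. Oxidative phosphorylation was higher (medians 0.14 and 0.24, adjusted p = 0.699 and 0.344 with an estimated correlation). Cox5b stood at 1.0, Ndufa7 at 0.70, Cox7c at 0.54 and Ndufa1 at 0.66 in BALB/c, and Ndufa1 at 0.89, Cox6a1 at 0.66, Ndufb8 at 0.51 and Atp5j at 0.56 (0.02 to 0.27 with its other probes) in C57BL/6. Fatty acid oxidation was called lower in BALB/c (median -0.23, adjusted p = 0.463 with an estimated correlation). Angptl4 stood at -3.11, Cpt2 at -0.94, Acot12 at least 2.51-fold lower and Ehhadh at -1.20. In C57BL/6 the colon had lower MHC class II genes (median -2.24, 9 of 12 fell, adjusted p = 0.176 with an estimated correlation), B cell markers (median -0.72, 11 of 20 fell, adjusted p = 0.44 with an estimated correlation) and interferon response genes (median -0.60, 13 of 32 fell, adjusted p = 0.553 with an estimated correlation). Among MHC class II genes, H2-DMa stood at -3.08, Cd74 at -2.63, H2-Ab1 at -2.71 and H2-Eb1 at -2.17. Among B cell markers, Vpreb3 stood at -1.47, Fcrla at -1.42, Ltb at -0.99 and Cd79b at -1.23. Among interferon response genes, Ddx58 stood at -1.34, Gbp2b at -2.09, Psmb8 at -1.89 and Oasl1 at -1.33 (-0.53 and -1.28 with its other probes). The strains shared 1822 genes higher in colon and 1232 lower, where independence gives 577 and 308, with 18 and 17 opposite. Fry called 24 and 25 lists, and 397 and 429 members passed adjusted over the list alone. Median scaling moved the median of all genes to 0.10 in BALB/c and 0.09 in C57BL/6, where the ribosomal protein list was no longer called in C57BL/6.

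**Figure D3:**
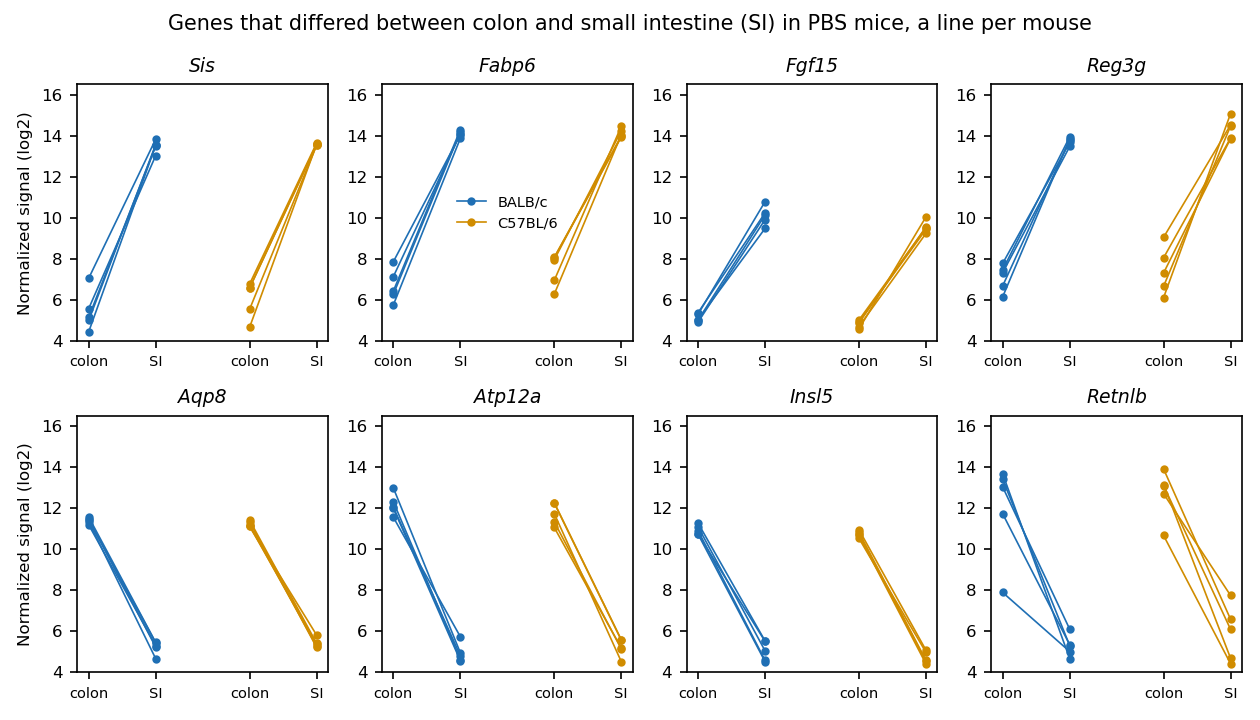
Normalized signal (log2) of 8 genes, chosen from those in the text, in colon and small intestine (SI) of the 5 PBS mice of each strain, with a line per mouse. Each line falls from small intestine to colon for Sis, Fabp6, Fgf15 and Reg3g and rises for Aqp8, Atp12a, Insl5 and Retnlb.

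Some colon arrays held transcripts of pancreatic acinar cells. The acinar score lay over 5 log2 above the median of the 20 colon arrays on 3 of them (BALB/c VSL#3 replicates 4 and 5 and C57BL/6 PBS replicate 3) and over 1 log2 above it on 7, of which 3 came from PBS and 4 from VSL#3 mice and 5 from BALB/c mice. Cela2a (pancreatic elastase) ranged from 4.75 to 15.28 over the colon arrays with a median of 5.50, Amy2a5 (pancreatic amylase) from 4.41 to 13.55 and the trypsin gene Try4 from 4.31 to 13.88. Several listed genes are expressed by the intestine too, as Zg16, Spink1, Clps, Cela1, Pnliprp1, Pnliprp2, Reg1 and Rnase1 were detected on 20 of 20 small intestine arrays, whereas Try4, Try5, Try10 and Cpb1 were detected on 0. Both thresholds of the score were set after the scores were seen.

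**Figure D4:**
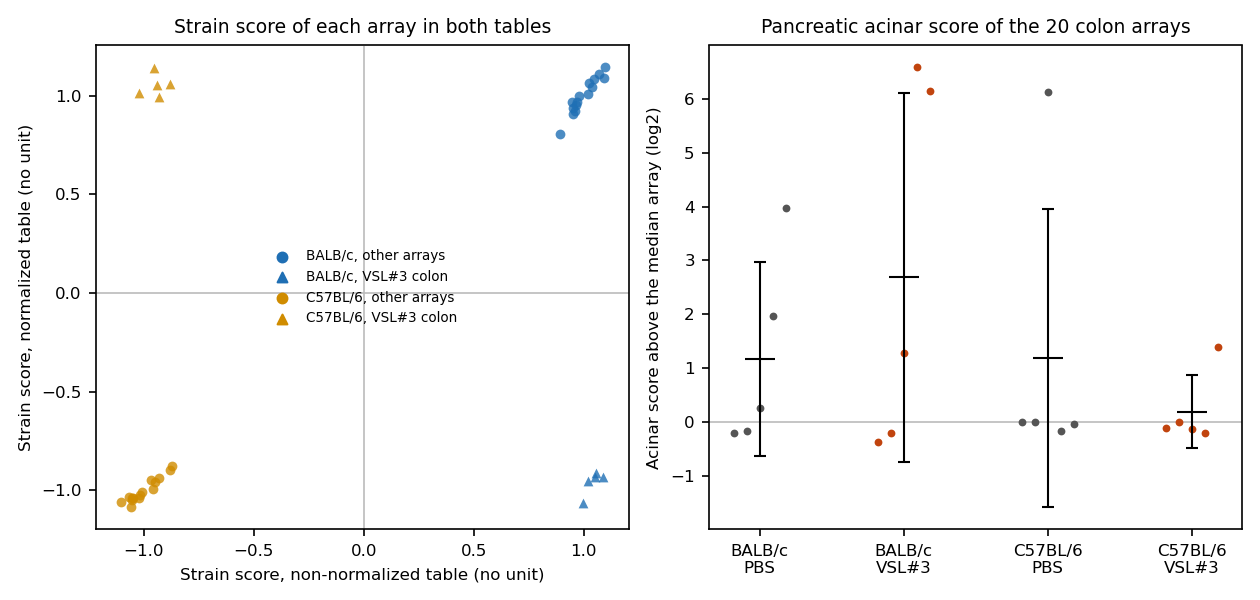
Left, the strain score of each array from 56 strain marker probes in the non-normalized (horizontal) and normalized (vertical) deposited tables, both without unit; right, the acinar score (log2) of the 20 colon arrays above their median, with points for mice and bars for the mean and SD of 5 mice. The 10 VSL#3 colon arrays (triangles) lie on opposite sides in the 2 tables, and the 3 highest acinar scores come from 2 groups.

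Clock genes varied between mice of a group. In BALB/c VSL#3 colon Dbp ranged from 7.36 to 11.75 (SD 1.92, n = 5), against 10.08 to 11.82 in BALB/c PBS colon (SD 0.64) and 6.51 to 7.33 in C57BL/6 PBS colon (SD 0.36). VSL#3 and PBS differed by -1.66 in Dbp in BALB/c colon (SE 0.58, adjusted p = 0.998). Without the 3 colon arrays with the highest acinar score they differed by -2.99 (adjusted p = 0.000193). This drops BALB/c VSL#3 mice 4 and 5. They had the highest clock scores of their group and its only letter B codes, so the larger difference follows from their removal.

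**Figure D5:**
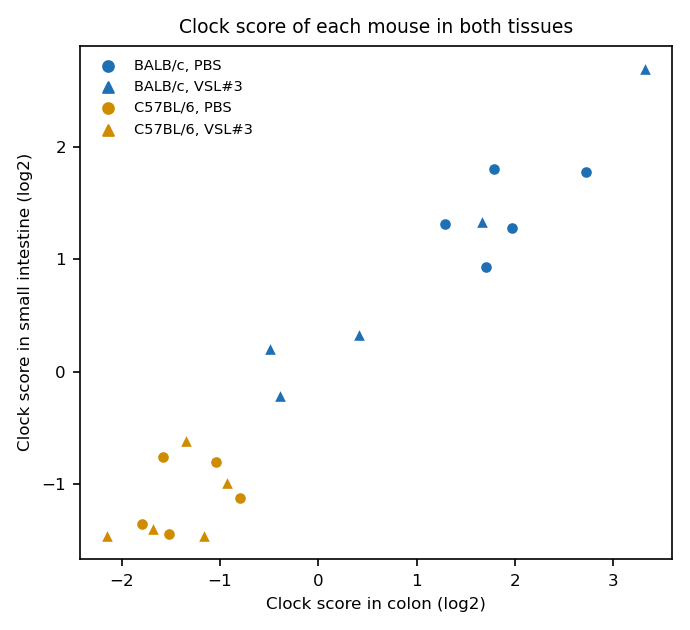
Clock score (log2; Dbp, Tef, Nr1d1 and Nr1d2 against Arntl and Npas2) of each of the 20 mice in colon (horizontal) and small intestine (vertical). Deviations of the 10 BALB/c mice from their group means correlated between the tissues (r = 0.939), and the scores of the 10 C57BL/6 mice spread less.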

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

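Chosen only after the results were seen were both tests of the deposited tables, the test of VSL#3 as the whole cause of the acinar transcripts, the islet test without 3 arrays, the thresholds of the acinar score and the reading of the probe test, which was changed from a difference of shares to a bound on the odds ratio.

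Single arrays stood apart from the other 4 of their group in 5 of 136 groups tested by the ratio of gap to range, where chance sets apart about 1 in 20 groups, or 6.8. They were C57BL/6 PBS colon replicate 3 in the acinar score (4.82), C57BL/6 VSL#3 colon replicate 5 in the acinar score (0.0936) and in the immediate early score (0.322), C57BL/6 PBS small intestine replicate 1 in the level of Il1b (5.68) and C57BL/6 PBS small intestine replicate 5 in the B cell score (-0.0285).

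Differences of the VSL#3 effect between strains or tissues stood out for lists that camera called in a test of the difference itself, and 0 of them held with an estimated correlation. In colon the medians of BALB/c minus C57BL/6 were 3.01 for pancreatic acinar markers, -0.589 for B cell and follicle markers, -0.704 for MHC class II antigen presentation, -0.203 for cholesterol synthesis, 0.197 for fatty acid oxidation and PPAR targets, -0.290 for T cell markers, -0.149 for macrophage and dendritic cell markers, 0.317 for adipocyte markers, -0.185 for circadian clock genes and 0.0680 for smooth muscle markers. In small intestine they were 0.648 for the interferon response, 0.333 for smooth muscle markers, -0.205 for cholesterol synthesis, -0.228 for absorptive genes, -0.378 for B cell and follicle markers, 0.618 for adipocyte markers and -0.114 for goblet cell and mucus genes. Colon minus small intestine in BALB/c gave 0.215 for xenobiotic metabolism, 1.37 for pancreatic acinar markers, -0.559 for adipocyte markers, -0.353 for the interferon response, 0.133 for absorptive genes and -0.143 for Toll-like receptor and NF-kB signalling. In C57BL/6 it gave 0.593 for MHC class II antigen presentation, 0.206 for the interferon response and 0.236 for B cell and follicle markers.

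For VSL#3 against PBS the real split called 0 genes in each of the 4 comparisons, so that 100 of 100 splits of the same arrays called as many by construction, which decides nothing, and the highest other split called 2 in BALB/c colon, 30 in C57BL/6 colon, 7 in BALB/c small intestine and 14 in C57BL/6 small intestine. As many gene lists were called in 79, 32, 7 and 41 of 100 splits, with 4, 8, 15 and 5 lists in the real split and at most 14, 18, 20 and 18 in another, so that chance was not excluded for any of them. For the strain difference of the effect the gene counts were likewise matched by construction in 100 of 100 splits in both tissues (0 real, at most 1 in colon and 11 in small intestine). The list counts were matched in 17 and 40 (10 and 7 real, at most 15 and 16). For the tissue difference the gene counts were matched by construction in 100 of 100 splits in both strains (0 real, at most 2 in BALB/c and 1 in C57BL/6), and the list counts in 51 and 79 (6 and 3 real, at most 16 and 14). The median of the other splits was 0 genes and 4 to 6 lists in these comparisons, and in C57BL/6 colon 11 of 99 called any gene, so that a chance extreme and a structure of the samples both stay open for the split with 30.

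Strain differences in PBS mice were matched by 1 of 100 splits in each tissue, the real one, with 1164 and 1052 genes against at most 6 and 7, which excludes chance for the gene counts. List counts of the strain comparison were matched by 23 and 30 of 100 splits (10 and 7 real, at most 15 and 16 in another), so that chance was not excluded for those. The 16 splits of the tissue comparison are too few for a share under 0.05. There the real split called 4129 genes in BALB/c and 4293 in C57BL/6 against at most 10 and 1398 in another, with 1 split as large in each, and 14 and 16 lists against at most 18 and 21, with 6 splits as large in each.

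The 10 VSL#3 colon columns of the normalized deposited table followed the same-numbered arrays of the other strain in the non-normalized table. Strain markers chosen from the other arrays put 10 of 10 of these columns on the other strain's side in the normalized table and 0 of 10 in the non-normalized table. These values are consistent with columns of the 2 strains exchanged in the deposited normalized table, and argue against columns of the 2 strains exchanged in the deposited non-normalized table. No biological explanation was tested, since both tables describe the same arrays.

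Pancreatic acinar transcripts were raised in some colon arrays. A PBS origin of 3 of the 7 arrays with a raised score argues against VSL#3 as the whole cause. Islet and acinar scores, as deviations from group means, correlated with r = 0.834 over the 20 colon arrays (permutation p = 4e-05), which rests on the 3 arrays over 5 log2, the only ones to detect Ins2, and pancreatic tissue in the colon sample may be the source there. Without these 3 arrays r was -0.187 (permutation p = 0.449), and pancreatic tissue in the 4 colon samples with a smaller acinar rise stays open, since Ins2 was detected on 0 of them and Iapp, the other islet gene (r = 0.416), on 5 colon and 7 small intestine arrays. A contribution of strain or treatment to how often it occurs stays open, since 5 of the 7 arrays came from BALB/c and 4 from VSL#3 mice.

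Among strain differences over 8-fold, more were lower in BALB/c (15 against 9 in colon and 22 against 9 in small intestine). A sequence variant under the probe could lower the signal in BALB/c if the probes follow C57BL/6 sequence, and the second probe would then show under 50% of the difference more often for genes called lower. The test took genes called at over 2-fold that had a second probe, not only those over 8-fold. In colon it did so for 15 of 33 genes lower against 11 of 31 higher (45.5% against 35.5%, Fisher's exact p = 0.455). In small intestine the share went the other way, 15 of 34 against 11 of 22 (44.1% against 50%, Fisher's exact p = 0.786). Too few genes with 2 probes keep this open. Of the genes called over 2-fold lower, second probes differed the same way by at least 50% for 54.5% in colon and 55.9% in small intestine. These shares go with expression differences at that threshold. Among genes over 8-fold lower, the second probe kept at least 50% for Ctsc in both tissues and Sprr2a1 in colon. It did not for Rmdn3 and Tor1aip2 in both tissues and Cfl2 in small intestine, so that the largest differences stay open. For single genes the 2 probes disagreed, as for H2-Q2 and Tor1aip2 in both tissues and Cfl2 in small intestine.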

How the results depend on the processing

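Chosen after the data were seen were the alternatives without 3 or 7 colon arrays, with the acinar score as a covariate, with values under 1 set to 1, the exact permutation test on list scores, and the list results without background correction and with median scaling.

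With the normalized deposited table, whose VSL#3 colon columns follow the other strain, 1177 genes passed for VSL#3 in BALB/c colon, 980 in C57BL/6 colon, 2036 for the strain difference of the effect in colon, and 901 and 587 for the tissue difference in BALB/c and C57BL/6. These counts follow from columns that carry the other strain. In BALB/c small intestine 1 gene passed with that table, without background correction and with values under 1 set to 1 (Mettl14 each time, adjusted p 0.0205, 0.0171 and 0.0218), and 1 with median scaling and with only the groups compared (Hspa1a, adjusted p 0.0203 and 0.0393). For C57BL/6 colon 1 gene passed with the replicate block (Ccn2, adjusted p = 0.0309). In the tissue difference in C57BL/6, 1 gene passed without background correction and with values under 1 set to 1 (Nfkbie, 1.40 and 3.96), and in BALB/c 1 with the acinar score as a covariate (Tnfrsf19, -1.01). The cause was not tested.

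Without the 3 colon arrays with the highest acinar score, and without the 7 with a raised score, 2 genes passed in BALB/c colon (Dbp -2.99 and -2.97, Tef -1.43 and -1.53) and 2 for the strain difference of the effect in colon (Dbp -2.84 and -2.89, Tef -2.06 and -2.30). Leaving out these arrays removes BALB/c VSL#3 replicates 4 and 5, whose clock scores were the highest of their group. The strain comparison in colon gave 683 genes without the 7 arrays, with fewer samples. List calls in BALB/c colon were 8 without 3 arrays, 7 without 7 and 8 with the covariate, and 5 in C57BL/6 colon without 3. In the tissue difference in BALB/c they were 13 without 3, 10 with the covariate and 2 with values under 1 set to 1. The acinar median reversed in BALB/c colon (-1.06, -0.15 and, with the covariate, -0.000464), in C57BL/6 colon (0.32 without 3 arrays, 0.00477 with the covariate), for the strain difference in colon (-1.42 and -0.0858) and for the tissue difference in BALB/c (-0.89 and -0.13), since these alternatives remove the score itself or the arrays that carry it. The interferon median of the tissue difference in BALB/c reversed to 0.19 and 0.22, where camera called the list in the opposite direction (adjusted p = 0.0270 and 0.0167). The cause was not tested.

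Camera with an estimated correlation and fry called 0 lists in each comparison of VSL#3 with PBS, in both strain differences and in both tissue differences of the effect. The exact permutation test on list scores, which does not cover the strain differences, called 0 in the others, where its smallest possible p of 0.00794 makes calls rare. In the strain comparison the estimated correlation left 0 lists in both tissues, and the exact test 8 in colon and 0 in small intestine. In the tissue comparison the estimated correlation left 3 in each strain, and fry called 24 in BALB/c and 25 in C57BL/6.

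H2-Q2 reversed with the normalized table, without background correction and with values under 1 set to 1 (-3.60, -2.33 and -3.61 in colon, -5.12, -3.83 and -5.12 in small intestine), where another of its probes was used. Tor1aip2 was 0.00405 in colon when only probes detected on every array were kept, which left another of its probes. Reg3g in small intestine lost its strain call with median scaling (-0.62), with the normalized table and with values under 1 set to 1 (adjusted p from 0.0580 to 0.0898). Of the values of named genes under alternatives that leave out no single array, 1149 in colon and 810 in small intestine kept their call in the strain comparison, or stayed uncalled within 1 residual standard deviation, and so did 1080 and 1158 in the tissue comparison of BALB/c and C57BL/6. There 10, 18, 7 and 8 lost their call, and the causes were not tested.

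Leaving out 1 array or mouse at a time, the genes past the threshold for VSL#3 ranged from 0 to 0 in BALB/c colon, 0 to 1 in C57BL/6 colon, 0 to 1 in BALB/c small intestine and 0 to 0 in C57BL/6 small intestine, and the lists from 2 to 7, 3 to 10, 7 to 16 and 1 to 11. The strain differences of the effect ranged from 0 to 1 genes and 6 to 14 lists in colon and from 0 to 0 genes and 6 to 9 lists in small intestine. The tissue differences ranged from 0 to 0 genes in both strains, with 0 to 14 lists in BALB/c and 1 to 6 in C57BL/6. Strain comparisons ranged from 962 to 1131 genes and 9 to 12 lists in colon and from 866 to 997 genes and 5 to 8 lists in small intestine. Tissue comparisons ranged from 3634 to 3799 genes and 14 to 16 lists in BALB/c and from 3815 to 4180 genes and 15 to 17 lists in C57BL/6. The acinar median in C57BL/6 colon ranged from -1.56 without PBS replicate 4 to 0.32 without PBS replicate 3, the array with the highest score of that group.

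No alternative for chip batches was run, since the files give no chip. A fit of only the groups compared has no value for the differences of effects, and lists were not computed with the normalized table for VSL#3 in colon and the comparisons within mice. Between 46.3% and 52.6% of probes were above background on an array, which limits the genes tested.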

Other observations

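Tests of the clock score were chosen after the values of single arrays had been seen, on genes of a list fixed before, and so were the comparison of strain differences between tissues and the splits of lists by code letter, while the gene test of the code letter was planned.

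Clock genes differed between mice of a group, and a difference between mice that both tissues share would make the scores of colon and small intestine correlate. They did so over the 10 BALB/c mice (r = 0.939, permutation p = 0.00017, rho = 0.842), as deviations from group means, also without the 2 mice farthest out (r = 0.850). Over the 10 C57BL/6 mice r was 0.414 (permutation p = 0.234), which leaves that strain open. The clock list in colon was also called higher with code letter B (median 0.29, adjusted p = 1.67e-05, and 0.0598 with an estimated correlation), and BALB/c VSL#3 mice 4 and 5, with the highest scores of their group, carry that letter. A difference in sampling time, which the labels do not give, and one that goes with the letter both stay open. Strain and time cannot be separated for Dbp.

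Source codes of the mice carry the letter A (12 mice) or B (8 mice). Each code number occurs in a single group, so that it cannot be separated from strain and treatment. Each full code holds 3 or 2 mice of its group. The letter was compared over all groups together, which cannot show a difference between single codes. Limma called 0 genes for the letter in colon and 0 in small intestine, with 611 and 335 at an unadjusted p under 0.05, and the highest other split of 100 called 1 and 6. Camera called 14 lists for the letter in colon, among them the interferon response (-0.49), circadian clock genes (0.29), pancreatic acinar markers (2.23) and MHC class II antigen presentation (-0.59), and 4 in small intestine. As many were called in 8 and 63 of 100 splits, the real one included, with at most 17 and 18 in another. With an estimated correlation MHC class II antigen presentation in colon alone was called (adjusted p = 0.0458), and 3 of 100 splits called as many as 1 list, with at most 1 in another. In small intestine 0 lists were called that way and at most 4 in another split. The planned reading, by which 0 genes would speak against a difference with the letter, was therefore dropped and the question stays open. Every group held 3 mice with A and 2 with B. Of the 7 colon arrays with a raised acinar score 5 carried the letter B.

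Strain differences themselves differed between the tissues of PBS mice for 283 of 9200 genes, 138 with a higher value of BALB/c minus C57BL/6 in colon and 145 with a lower one. For Cfl2 the difference was 6.11, with means of 6.36 in BALB/c and 6.41 in C57BL/6 colon and of 5.85 and 12.01 in small intestine, and its second probe showed no such difference in small intestine (-0.03).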
